A study of Homo sapiens with 92 samples.

How the data were processed

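RNA was measured in 92 kidney biopsies of 7 groups, 1 array per biopsy, in groups of 10, 13, 4, 13, 15, 12 and 25. Per the labels' protocols, 1 core of each biopsy was kept in RNAlater and checked for kidney tissue under a dissecting microscope. RNA was isolated with a QIAGEN RNeasy Mini kit, samples with an RNA integrity number above 7 were used, and RNA was amplified with the Ambion whole-transcript kit, labelled with biotin and hybridised to Affymetrix arrays. The deposited values are log2 intensities per transcript cluster. Per the submitters' processing notes they were made with RMA, which corrects background, makes the probe distributions of the arrays equal and summarises the probes of a cluster, through the oligo package, and limma is also named. The log base is that of RMA, and the versions of these upstream tools are not given in the sources used here. The array medians of 6.48 to 6.76 lie close together, in keeping with a shared normalisation. The labels give no hybridisation batch or date, and nothing says whether 2 biopsies share a donor. Titles carry a running number, and 1 such number stands in the titles of both a native and a reference biopsy; whether it marks a person, a pair or an order of collection is not stated. P-values therefore measure the spread between these biopsies.

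Of 29096 transcript clusters 19460 carry 1 gene symbol, 1754 several and 7882 none. For each symbol the cluster with the highest mean over all arrays was used among those with 1 symbol, which left 18417 genes, 769 of them with more than 1 such cluster. Clusters with several symbols or none were left out of the comparisons, since their signal cannot be given to 1 gene. They were tested apart from these, in a fit of all 29096 clusters with adjustment over all of them. No filter on dim probes and no further normalisation was applied.

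All comparisons came from 1 model in limma 3.58.1 (R 4.3.3) with a mean for each of the 7 groups (lmFit, contrasts.fit, eBayes, two-sided), so that every comparison shares 1 estimate of each gene's spread. A gene changed when its Benjamini-Hochberg adjusted p over the 18417 genes was under 0.05. The comparisons set each transplant group against the native biopsies, each other transplant group against the reference biopsies (C4d-negative without glomerular disease), glomerular C4d with disease against C4d-negative with disease and against glomerular C4d without disease, and peritubular capillary C4d against both glomerular C4d groups. An interaction tests whether the difference that goes with disease depends on glomerular C4d. The number of biopsies showing a direction is that beyond the median of the group compared with.

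The comparisons, the tests, 29 gene lists with 523 members and the rule for naming genes were fixed before the data were examined. The lists come from general knowledge of immune responses, cell types, nephron segments, injury and metabolism, and 468 of their members were measured. Each list was tested in each of 15 comparisons of groups with limma's camera, which asks whether a list's genes rank higher or lower than all others, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all 435 tests. Genes of 1 cell type vary together far more than that, so every list was also tested with a correlation estimated from these arrays, and the text says which calls hold with it. Limma's fry, which tests whether a list's genes move on balance one way without comparing them with other genes, was run as well. Counts of list members are given over all genes and adjusted over the list alone. Named genes are the 10 largest rises and falls among genes past the threshold in the main comparisons (5 in the others), up to 4 members of each shifted list with the largest change past the threshold, and 11 genes preset by name. Results are given for part of these.

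The procedure was tested on simulated data with the same group sizes, 18417 genes and 50 genes moved by each of 4 sizes. Of changes of 1 on the log2 scale it recovered 96 percent in the sizes of reference against native biopsies and of peritubular capillary C4d against reference biopsies, 92 percent in those of glomerular C4d with disease, and 76 percent in those of the minimal group, with 7 to 11 false calls. A list whose 20 genes were all moved by 0.5 was called in each of these 4 comparisons, the 1 size of shift tried for a list. The simulated genes varied independently of each other, so this says nothing on lists of genes that vary together. Genes moved by all 4 sizes were drawn at random and changed together in 1 run, so recovery need not hold where few genes change.

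Alternatives fixed before the data were examined were to leave out dim genes (under the 40th percentile of means), to average all clusters of a gene, to weight arrays with limma's arrayWeights, to fit only the groups compared, to quantile-normalise again, to add the running number in the sample titles as a covariate, in case it is an order of collection, to leave out the 6 biopsies with another visit tag, to add each biopsy's collecting duct or podocyte list mean as a covariate, to require a change of 1.5 times, eBayes with trend and robust options, and to leave out each minimal PTC C4d biopsy in turn. After seeing the data, the array spread was added as a covariate, the 10 arrays whose spread lay under the lower quartile by more than 1.5 interquartile ranges were left out, the 2 biopsies with very low proximal tubule genes were left out, and each biopsy was left out in turn in the comparison of reference with native biopsies and in those between transplant groups that do not involve the minimal group. For 100 random splits of the biopsies of a comparison the genes past the threshold were counted again. Values beyond Dixon's limit were looked for in the groups of 4 and 10 over 29 list means, 72 genes and the array spread. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures. Raw probe intensities were not used here.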

Results

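RNA from 92 kidney biopsy cores was measured on a human whole-transcript expression array, with 1 array per biopsy. C4d, a fragment of complement component C4 that stays bound to tissue after antibody has activated complement, was stained in the transplant biopsies, and the labels group them by where it was seen. The groups are 10 native kidneys sampled before implantation (native biopsies), 13 transplants with focal or diffuse C4d in the peritubular capillaries (PTC C4d biopsies), 4 with minimal C4d there (minimal PTC C4d biopsies), 13 and 15 with C4d in glomeruli alone and with or without glomerular disease (glomerular C4d biopsies with disease and without disease), 12 that were C4d-negative with glomerular disease (C4d-negative biopsies with disease), and 25 that were C4d-negative without it (reference biopsies). Changes are differences of group means on the log2 scale, given with their standard error, and levels are log2 intensities given as mean ± SD. The array medians lay between 6.48 and 6.76. The spread of an array's log2 values, its SD over all transcript clusters, ran from 1.72 to 2.17. It averaged 1.98 ± 0.0984 in the native biopsies and 2.07 ± 0.0913 in the reference biopsies, so an array measure also moved with that comparison. The number of arrays, above all the 4 of the minimal group, limits the precision.

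The comparison of reference with native biopsies shows what separates a transplanted kidney without C4d or glomerular disease from a kidney before implantation. Genes of early cell activation were lower in the transplants. Of 25 measured immediate-early and stress genes, which cells switch on within minutes of a stimulus, 16 fell and the other 9 did not pass the test (17 fell when adjusted over the list alone). FOS and EGR1, transcription factors of that response, fell by 1.68 and 1.62 on the log2 scale (SE 0.212 and 0.193, adjusted p = 2.49e-08 and 3.78e-09). The nuclear receptors NR4A2 and NR4A1 fell by 1.55 and 1.30. Each of these genes lay under the native median in 25 of 25 reference biopsies. The list mean was 7.62 ± 0.193 in the reference biopsies (n = 25) and 8.23 ± 0.467 in the native ones (n = 10), and its call held with an estimated correlation (adjusted p = 0.0267).

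Genes of immune cells rose in the same comparison. Of 22 macrophage and monocyte genes 16 rose and 1 fell (18 and 1 adjusted over the list alone), with LYZ, the bacteriolytic enzyme lysozyme, higher by 2.56 ± 0.365 (adjusted p = 8.7e-07, above the native median in 25 of 25). Of 20 T cell genes 12 rose (14 over the list alone), among them CD3G, a chain of the T cell receptor complex, by 1.90 ± 0.358. IL2RG, the shared receptor chain of several interleukins, and PTPRC, the leukocyte antigen CD45, were higher by 2.19 and 1.99. In the interferon-gamma-inducible list 17 of 22 rose (19 over the list alone), and in the type I interferon-stimulated list 14 of 25 (17). Rises also passed the gene test for 10 of 23 cytotoxic and NK cell genes (12 over the list alone), 5 of 15 B cell and plasma cell genes (5), 5 of 7 MHC class II genes (5), 8 of 23 endothelial genes (10) and 8 of 24 genes associated with antibody-mediated rejection (10). All of these lists ranked above other genes with the preset correlation of 0.01, but none kept its call with an estimated one. The adjusted p with an estimated correlation was 0.414 for macrophages, 0.459 for T cells, 0.381 and 0.44 for the interferon lists, 0.543 for cytotoxic cells, 0.684 for B cells, 0.392 for MHC class II, 0.436 for endothelium and 0.388 for rejection.

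Complement, matrix and injury genes were higher in the reference biopsies too. C1S, a protease of the first complement complex, rose by 1.81 ± 0.233 and C3, the central complement protein, by 1.66 ± 0.439, with 11 of 20 complement genes past the test (13 over the list alone, adjusted p = 0.241 with an estimated correlation). VCAN and LUM, proteoglycans of the extracellular matrix, rose by 1.62 and 1.42, with 13 of 24 matrix and fibrosis genes (17 over the list alone, adjusted p = 0.4 with an estimated correlation). MMP7, a matrix-degrading protease, SERPINA3, an acute-phase protease inhibitor, and HAVCR1, the injury marker KIM-1, rose by 1.92, 1.92 and 1.29 among 12 of 29 tubular injury and repair genes (13 over the list alone, adjusted p = 0.512 with an estimated correlation). Genes of the distal nephron were lower, with EGF and the protease gene KLK1 at -1.35 and -1.31 and the magnesium channel TRPM6 at -1.08, 3 of 13 thick limb and distal tubule genes having fallen (3 over the list alone, adjusted p = 0.585 with an estimated correlation). PDK4, a kinase that restrains glucose oxidation and responds to glucocorticoids, fell by 1.49 among 3 of 11 glucocorticoid-responsive genes (5 over the list alone, adjusted p = 0.38 with an estimated correlation). The urothelium list ranked lower with no gene of 7 past the test (adjusted p = 0.463 with an estimated correlation).

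In limma's test of 18417 genes, 3625 changed between reference and native biopsies, of which 2148 rose and 1477 fell. With the array spread as a covariate, chosen after seeing the data, 1856 changed and the balance turned, with 813 rising and 1043 falling. The count was 8098 with arrays weighted (4411 rising, 3687 falling), 6443 without the 10 arrays of lowest spread, 5540 with the running number as a covariate and 2229 without native replicate 5. Transcript clusters left out of the comparisons, tested apart, went mostly the other way. Of 1754 with several symbols 156 rose and 407 fell, and of 7882 without a symbol 159 rose and 1755 fell. Of the 29 lists 16 shifted, 12 upward and 4 downward, and 1 held with an estimated correlation, the immediate-early list.

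**Figure D1:**
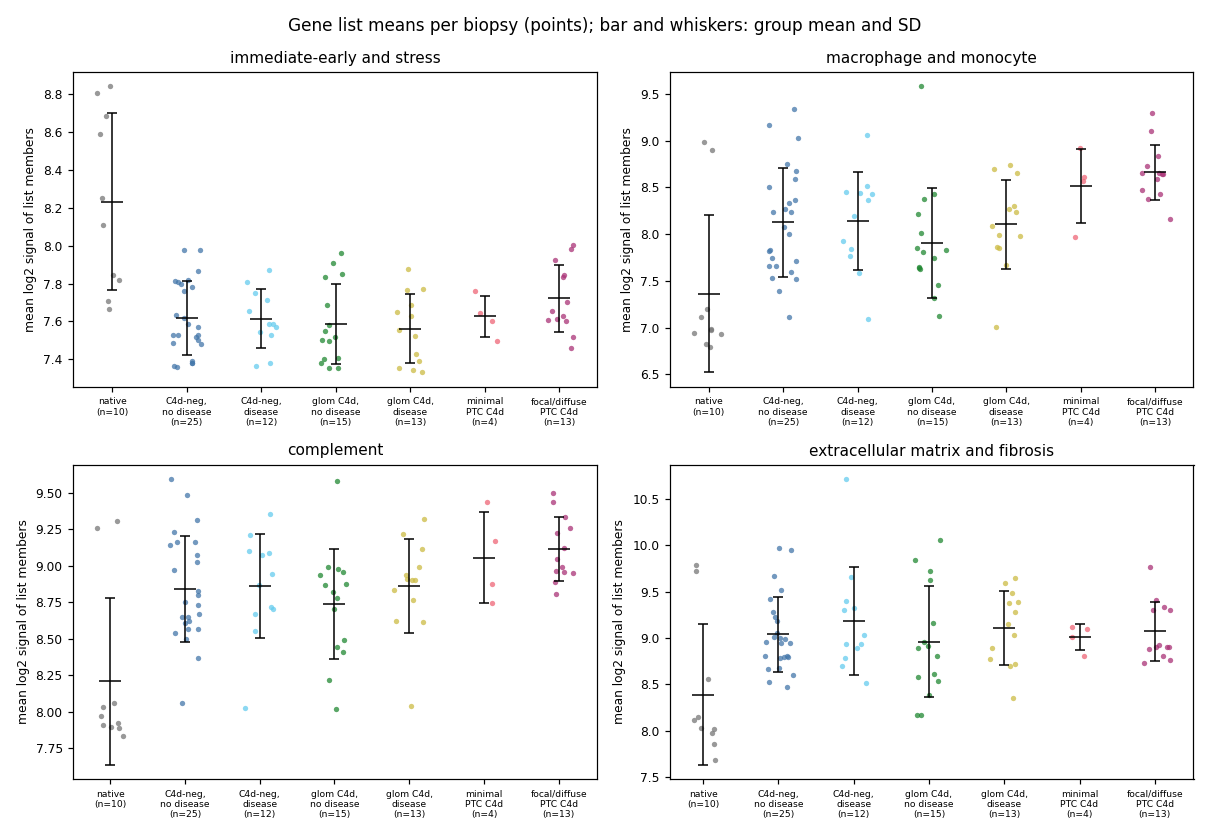
Mean log2 intensity of 4 gene lists (immediate-early and stress, macrophage and monocyte, complement, extracellular matrix and fibrosis) in each biopsy, by group, on the vertical axis, with 1 point per biopsy, and a bar for each group's mean with its SD. The immediate-early mean was 8.23 ± 0.467 in the 10 native biopsies and 7.62 ± 0.193 in the 25 reference biopsies.

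Each of the other transplant groups was also compared with the native biopsies, and the immediate-early genes were lower in all of them. FOS changed by -1.56 in PTC C4d biopsies, -1.66 in minimal PTC C4d biopsies, -1.70 and -1.63 in glomerular C4d biopsies with and without disease and -1.54 in C4d-negative biopsies with disease, each past the test. Among the 25 genes of that list 14, 14, 16, 15 and 15 fell in these groups, in that order (15, 15, 18, 17 and 16 adjusted over the list alone). LYZ was higher in every one, by 2.12 to 3.31, and LUM by 1.46 to 1.86. The largest rise was that of JCHAIN, which links the subunits of secreted immunoglobulin, in minimal PTC C4d biopsies (4.40 ± 1.08, above the native median in 4 of 4), and it was 4.18 in PTC C4d biopsies. In PTC C4d biopsies CXCL9, a T cell attractant induced by interferon gamma, rose by 4.09 ± 0.612 (13 of 13). With an estimated correlation the immediate-early call held in some of these groups, at adjusted p = 0.0272, 0.0267 and 0.0272 in the glomerular C4d biopsies with and without disease and the C4d-negative biopsies with disease, and was lost in the PTC C4d and the minimal group (adjusted p = 0.165 and 0.141).

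The rises of the PTC C4d biopsies over native covered 21 of 22 interferon-gamma-inducible genes (21 over the list alone), 17 of 23 endothelial genes (17) and 23 of 24 rejection-associated genes (23), and these lists kept their calls with an estimated correlation (adjusted p = 0.0419, 0.0465 and 0.0073). Genes of podocytes, the filter cells of the glomerulus, fell in glomerular C4d biopsies with disease, 7 of 12 (7 over the list alone), among them PTPRO, a podocyte membrane phosphatase, by 1.35 and NPHS1, the slit diaphragm protein nephrin, by 0.81; the call was lost with an estimated correlation (adjusted p = 0.286). In limma's test 3050 genes changed in PTC C4d biopsies (1873 rose, 1177 fell), 1232 in the minimal group (847 and 385), 3216 and 2745 in glomerular C4d biopsies with disease (1934 and 1282) and without (1483 and 1262), and 1998 in C4d-negative biopsies with disease (1169 and 829). The lists shifted numbered 20, 15, 19, 15 and 17 in the same order, of which 3, 0, 1, 1 and 1 held with an estimated correlation. With the array spread as a covariate the rises and falls numbered 1766 and 2321, 328 and 407, 989 and 1644, 244 and 608, and 984 and 1572, so that falls outnumbered rises in each. With arrays weighted the counts were 8432 (4044 and 4388), 6613 (3254 and 3359), 8295 (4130 and 4165), 9077 (4636 and 4441) and 7309 (3823 and 3486). Without replicates 11 and 2 of the glomerular C4d biopsies with disease, which had low proximal tubule genes, that group's count was 1701 (916 and 785). The minimal group's count rested on single biopsies: it was 142 without replicate 1, 407 without replicate 3 and 433 without replicate 2. Transcript clusters without a symbol, tested apart, mostly fell in each group. Rises and falls were, in the same order, 176 and 733, 72 and 296, 158 and 1136, 112 and 1115, and 109 and 667. Among clusters with several symbols they were 141 and 194, 80 and 57, 148 and 189, 95 and 344, and 140 and 100.

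**Figure D2:**
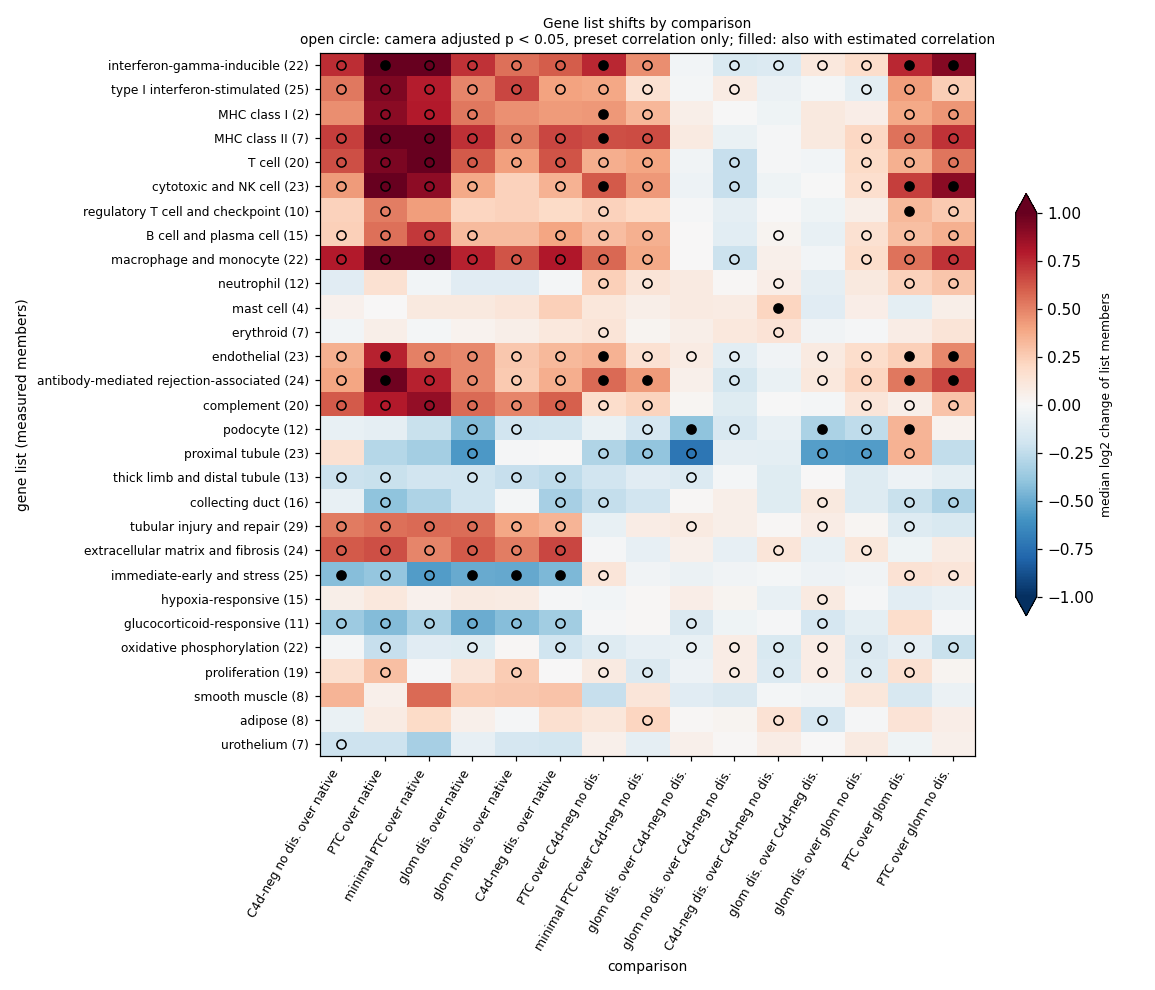
Median log2 change of each of the 29 gene lists (vertical axis) in each of the 15 comparisons of groups (horizontal axis), coloured from -1 to 1. An open circle marks a list shifted with the preset correlation alone (199 cells) and a filled circle one that held with an estimated correlation (27 cells), and 8 medians lie beyond the colour scale.

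The comparison of PTC C4d biopsies with reference biopsies asks what goes with C4d along the capillaries between the tubules. Interferon-gamma-inducible genes and genes of cytotoxic cells and endothelium were higher. The chemokines CXCL10, CXCL11 and CXCL9, which draw activated T cells and NK cells, rose by 1.97 ± 0.448, 1.94 ± 0.415 and 1.92 ± 0.497 (adjusted p = 0.019, 0.01 and 0.049; above the reference median in 12, 13 and 13 of 13 biopsies). IDO1, an enzyme that breaks down tryptophan, UBD, a ubiquitin-like protein, and the guanylate-binding proteins GBP5 and GBP4 rose by 1.60, 1.20, 1.71 and 1.22. In that list 14 of 22 genes rose (19 adjusted over the list alone), and its mean was 8.88 ± 0.437 in PTC C4d biopsies (n = 13) and 8.01 ± 0.683 in reference biopsies (n = 25).

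The gene with the lowest adjusted p was SH2D1B, a signalling adaptor of NK cells, at 1.26 ± 0.17 (adjusted p = 1.2e-06, 12 of 13). FCGR3A, the Fc receptor CD16 that binds antibody on NK cells and monocytes, rose by 1.08, PRF1, the pore-forming protein perforin, by 0.83, and CTSW, a cathepsin of cytotoxic cells, by 0.80. These are among 5 of 23 cytotoxic and NK cell genes that rose (20 over the list alone). GNLY, the granule protein granulysin, was at 0.63 (adjusted p = 0.0772) and did not pass. SLAMF7, a receptor of NK and plasma cells, and TNFRSF9, a costimulatory receptor of activated lymphocytes, rose by 1.57 and 1.17. Of 23 endothelial genes 6 rose (15 over the list alone), among them VWF, the von Willebrand clotting factor, by 0.95, the junction protein CDH5 by 0.58 and the adhesion molecule PECAM1 by 0.57. B2M, the light chain of MHC class I, rose by 0.56, and HLA-DOA, an MHC class II chain, by 0.59. TAPBP, the other measured member of the MHC class I list, passed over the list alone, as did all 7 class II genes. Only 2 of the 8 members fixed for the class I list were measured, so it rests on B2M and TAPBP. In the rejection-associated list, of which 17 members stand on another list, 13 of 24 genes rose (23 over the list alone), PLA1A, a phospholipase, by 0.77, PALMD by 0.64 and KLF4, a transcription factor of endothelium, by 0.51.

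The lists that held with an estimated correlation were the interferon-gamma-inducible (adjusted p = 0.021), cytotoxic and NK cell (0.0173), endothelial (0.0163), MHC class I (0.0319), MHC class II (0.0321) and rejection-associated list (9.46e-05). T cell genes did not pass singly, 0 of 20 and 0 over the list alone, and that list's upward shift was lost with an estimated correlation (adjusted p = 0.42). The macrophage list shifted upward with 0 of 22 genes past the test and 16 over the list alone (adjusted p = 0.141 with an estimated correlation). Upward shifts lost in the same way were those of type I interferon (adjusted p = 0.29 with an estimated correlation), checkpoint (0.0631), B cell (0.414), neutrophil (0.174), erythroid (0.478), complement (0.278), immediate-early (0.512) and proliferation genes (0.687). The proximal tubule, collecting duct and oxidative phosphorylation lists ranked lower, with no gene past the test and adjusted p = 0.684, 0.54 and 0.511 with an estimated correlation. The 5 genes that fell were LSM3, a factor of RNA splicing, by 0.47, AP2M1, an adaptor of endocytosis, by 0.31, the small GTPase RAB38 by 0.30, and PARP16 and the mitochondrial ribosome factor MRRF by 0.28 each. The injury markers HAVCR1 and LCN2 were at -0.44 (adjusted p = 0.75) and -0.15 (adjusted p = 0.864).

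In limma's test 86 genes changed, 81 up and 5 down (1902 at an unadjusted p under 0.05), and 19 lists shifted (16 upward, 3 downward). The count ran from 20 to 171 when single biopsies were left out, at 20 without PTC C4d replicate 3 and 22 without replicate 2, and was 10 without the 6 biopsies whose titles carry another visit tag than the rest. With arrays weighted by their quality 1221 genes changed, 610 up and 611 down, and without the 10 arrays of lowest spread 324, 193 up and 131 down, so the balance of rises over falls rests on how the arrays count. SH2D1B, CXCL11, IDO1, UBD, TNFRSF9, PRF1 and PECAM1 passed in all 38 fits that left out 1 biopsy, CXCL9 in 13, HLA-DOA in 13 and VWF in 16.

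**Figure D3:**
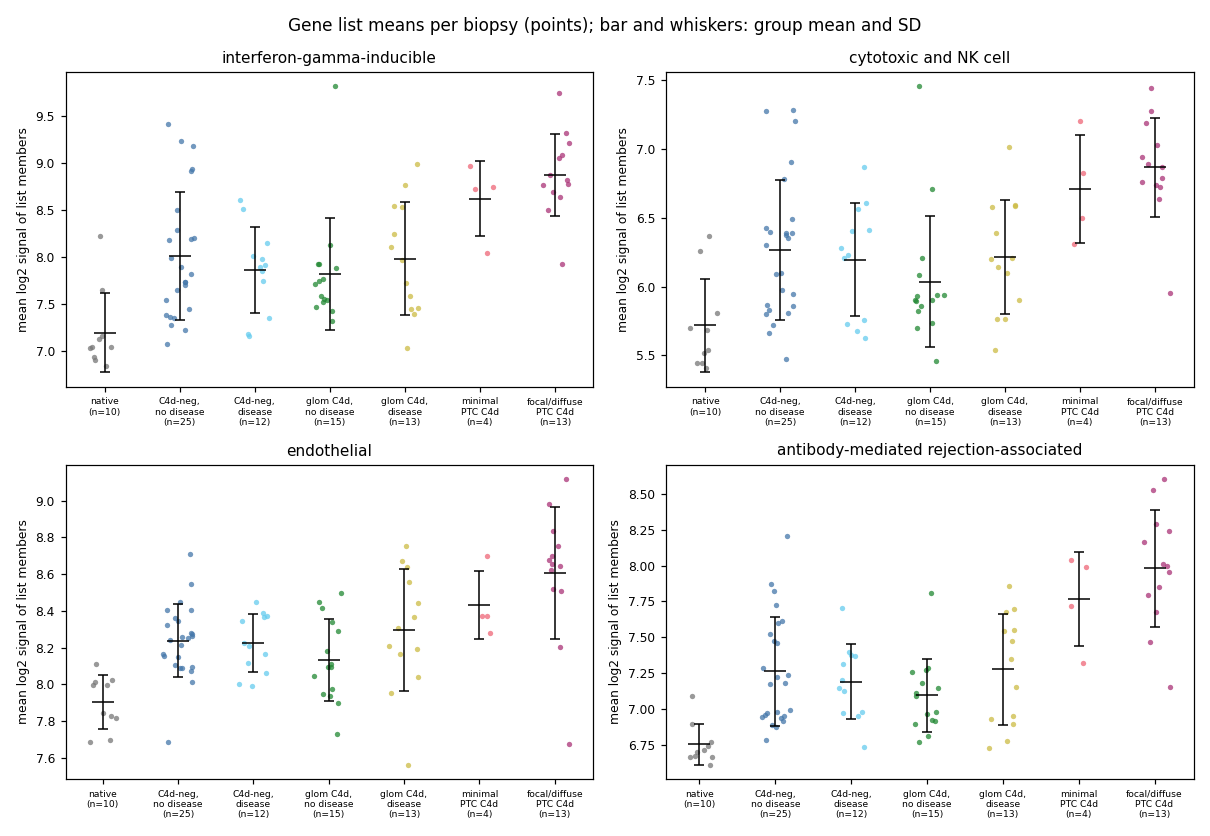
Mean log2 intensity of 4 gene lists (interferon-gamma-inducible, cytotoxic and NK cell, endothelial, rejection-associated) in each biopsy, by group, on the vertical axis, with 1 point per biopsy and a bar for each group's mean with its SD. The rejection-associated mean was 7.98 ± 0.406 in the 13 PTC C4d biopsies and 7.26 ± 0.38 in the 25 reference biopsies.

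Minimal PTC C4d biopsies were compared with reference biopsies to see whether minimal capillary staining goes with a change of its own. The rejection-associated list was higher, with a mean of 7.77 ± 0.327 (n = 4) against 7.26 ± 0.38 (n = 25), and its call held with an estimated correlation (adjusted p = 0.0233, range over 11 alternatives 5.94e-17 to 0.0304). In this range all alternatives but the estimated correlation and fry used the preset correlation of 0.01. None of the 24 genes of the rejection-associated list passed over all genes and 2 passed over the list alone. CXCL9 stood at 1.62 ± 0.783 and PRF1 at 0.59 ± 0.271, above the reference median in 4 and 3 of 4, and neither passed (adjusted p = 0.999 each). Interferon-gamma-inducible, cytotoxic, MHC class II, macrophage and T cell genes shifted upward with the preset correlation alone (adjusted p = 0.223, 0.214, 0.156, 0.392 and 0.465 with an estimated correlation). The proximal tubule list shifted downward (adjusted p = 0.67 with an estimated correlation), with replicate 1 far below the other biopsies of the group. In all, 16 lists shifted (13 upward, 3 downward) and 1 held with an estimated correlation. By limma 0 genes changed (276 at an unadjusted p under 0.05, and 0 with arrays weighted). In a simulation of these group sizes a change of 1 on the log2 scale was recovered for 38 of 50 genes. That simulation moved many randomly drawn genes at once. It does not show that changes of this size are absent here, above all in genes as variable as CXCL9.

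Glomerular C4d biopsies with disease were set against reference biopsies, against C4d-negative biopsies with disease and against glomerular C4d biopsies without disease. Podocyte genes were lower in them. Against reference biopsies PTPRO fell by 1.05 (SE 0.214, under the reference median in 11 of 13) and CLIC5, a protein of podocyte foot processes, by 0.84 (0.176, 11 of 13), each with an adjusted p of 0.0439. NPHS1 was at -0.66 (adjusted p = 0.135) and did not pass. Of 12 podocyte genes 2 fell and 8 fell adjusted over the list alone, with a list mean of 7.88 ± 0.395 (n = 13) against 8.32 ± 0.201 (n = 25). The call held with an estimated correlation (adjusted p = 0.00174, range over 10 alternatives 2.75e-24 to 0.00174). Against C4d-negative biopsies with disease the list mean was lower as well (8.26 ± 0.344, n = 12; 6 of 12 genes over the list alone), and this call held too (adjusted p = 0.00695 with an estimated correlation, range over 10 alternatives 1.69e-20 to 0.00968). In both ranges all alternatives but the estimated correlation and fry used the preset correlation of 0.01. Those without a minimal PTC C4d biopsy removed no biopsy of the groups compared. Against glomerular C4d biopsies without disease (8.16 ± 0.323, n = 15) the downward shift was lost with an estimated correlation (adjusted p = 0.217), with 3 genes past the test over the list alone.

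Proximal tubule genes ranked lower against reference biopsies, with a list mean of 10.56 ± 1.66 against 11.25 ± 0.441, no gene of 23 past the test (2 over the list alone) and adjusted p = 0.236 with an estimated correlation. Replicates 11 and 2 of this group had proximal tubule means of 6.74 and 7.13, where the other 11 averaged 11.22 ± 0.464, and collecting duct means of 9.43 and 9.94 against 8.41 ± 0.441 in the other arrays. Without them, an alternative chosen after seeing the data, the proximal tubule difference went from -0.69 to -0.028 and the podocyte difference from -0.44 to -0.37 (7.95 ± 0.385, n = 11; adjusted p = 0.00875 with an estimated correlation). Thick limb, glucocorticoid-responsive and oxidative phosphorylation genes also ranked lower (adjusted p = 0.589, 0.559 and 0.703 with an estimated correlation), and endothelial and tubular injury genes higher (0.659 and 0.702).

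**Figure D4:**
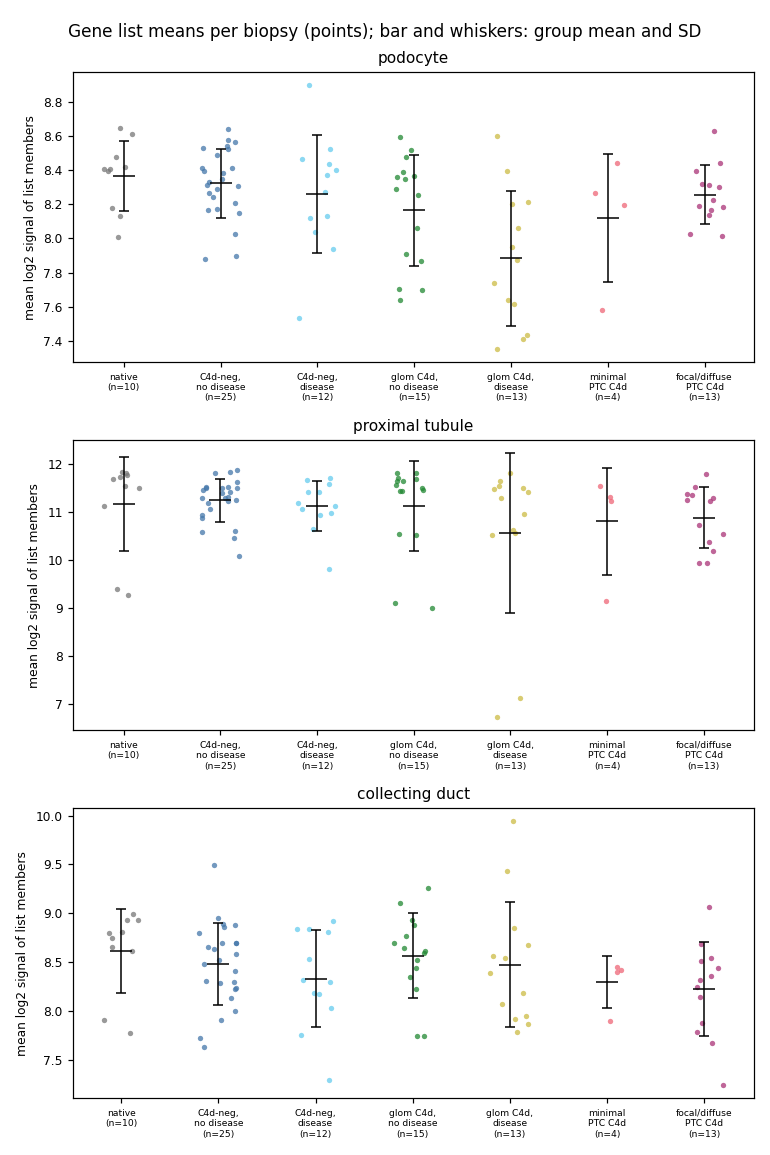
Mean log2 intensity of 3 gene lists (podocyte, proximal tubule, collecting duct) in each biopsy, by group, on the vertical axis, with 1 point per biopsy and a bar for each group's mean with its SD. The podocyte mean was 7.88 ± 0.395 in the 13 glomerular C4d biopsies with disease, and the 2 lowest proximal tubule means, 6.74 and 7.13, belong to the same group.

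By limma 3 genes changed against reference biopsies, PTPRO, CLIC5 and the long non-coding RNA gene LINC00839 (-0.47 ± 0.0977), all lower (652 at an unadjusted p under 0.05; 27 with arrays weighted, 1 up and 26 down). No gene passed without those 2 biopsies, and the count was 0 in 25 of the 38 fits that left out 1 biopsy. Against C4d-negative biopsies with disease 0 genes changed (251 at an unadjusted p under 0.05; 0 with arrays weighted) and 12 lists shifted (8 upward, 4 downward), 1 of them also with an estimated correlation. Against glomerular C4d biopsies without disease 0 genes changed (947 at an unadjusted p under 0.05, lowest adjusted p = 0.0575; 710 with arrays weighted, 242 up and 468 down) and 15 lists shifted (10 upward, 5 downward), 0 with an estimated correlation; leaving out 1 biopsy at a time gave 0 to 3 genes. The interaction, whether the difference that goes with disease depends on glomerular C4d, found 0 genes by limma (346 at an unadjusted p under 0.05; 5 with arrays weighted), with NPHS1 at -0.43 ± 0.233 (adjusted p = 1).

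In glomerular C4d biopsies without disease, compared with reference biopsies, PFKFB1, an enzyme that sets the level of a regulator of glycolysis, rose by 0.88 ± 0.159 (adjusted p = 0.00598, above the reference median in 12 of 15). No inflammatory gene named here passed the test. CXCL9 was at -0.32 ± 0.475, CXCL10 at -0.26 ± 0.428, PRF1 at -0.29 ± 0.164 and the podocyte gene NPHS1 at -0.16 ± 0.148, all short of it. The cytotoxic, rejection-associated, endothelial, T cell, macrophage and podocyte lists ranked lower with the preset correlation alone (adjusted p = 0.388, 0.388, 0.467, 0.559, 0.577 and 0.364 with an estimated correlation), as did the interferon-gamma-inducible list (0.626), and no member of these passed the gene test. Type I interferon-stimulated, oxidative phosphorylation and proliferation genes ranked higher in the same way (adjusted p = 0.67, 0.659 and 0.662 with an estimated correlation), also with no member past the gene test. By limma 1 gene changed (706 at an unadjusted p under 0.05; 1042 with arrays weighted, 493 up and 549 down), and 10 lists shifted (3 upward, 7 downward), 0 with an estimated correlation. PFKFB1 did not pass without glomerular C4d replicate 13 of the group without disease. Its mean lay under the 40th percentile, so leaving out dim genes took it out of the test. PFKFB1 did not pass after quantile normalisation again either, nor when only the groups compared were fitted. Replicates 11 and 13 of this group were more alike than any other pair of arrays (r = 0.995). Whether they come from the same kidney is not stated and was not tested, so they may not be independent. The count stayed at 1 without replicate 11.

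In C4d-negative biopsies with disease, compared with reference biopsies, mast cell genes were higher, with a list mean of 6.45 ± 0.323 (n = 12) against 6.17 ± 0.306 (n = 25). The list of 4 genes held with an estimated correlation (adjusted p = 0.0233, range over 11 alternatives 2.42e-04 to 0.0233), with 0 past the test over all genes and 1 over the list alone. Oxidative phosphorylation genes ranked lower (1 of 22 over the list alone, adjusted p = 0.388 with an estimated correlation), and matrix and adipose genes higher (adjusted p = 0.659 and 0.341 with an estimated correlation). NPHS1 was at -0.067 ± 0.159, HAVCR1 at 0.25 ± 0.38 and CXCL9 at -0.30 ± 0.511, none past the test. By limma 0 genes changed (775 at an unadjusted p under 0.05; 101 with arrays weighted, 10 up and 91 down), and 9 lists shifted (6 upward, 3 downward).

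PTC C4d biopsies were compared directly with the glomerular C4d groups. The labels call only the glomerular staining isolated, so PTC C4d biopsies may have glomerular C4d as well. Whether they had glomerular disease is not stated either, so these comparisons do not separate the place of staining from disease. Against glomerular C4d biopsies with disease CXCL10 rose by 2.39 ± 0.514, CXCL11 by 2.05 ± 0.476, IDO1 by 1.69 ± 0.375 and SH2D1B by 1.29 ± 0.195 (adjusted p = 5.06e-05, 12 of 13). TNFRSF9, the chemokine CCL4, the inhibitory receptor LILRB2 of myeloid cells and STX11, a protein of granule release, rose by 1.29, 0.89, 1.03 and 1.04. PODXL, a surface sialoprotein of podocytes and endothelium, rose by 0.63, the 1 gene of 12 in the podocyte list to pass (8 over the list alone). LRRC1 fell by 0.36. The lists that held with an estimated correlation were the rejection-associated (6 of 24 rose, 19 over the list alone, adjusted p = 9.46e-05), cytotoxic (3 of 23, 18, 0.0124), interferon-gamma-inducible (4 of 22, 19, 0.0163), podocyte (0.0267), checkpoint (1 of 10, 2, 0.0321) and endothelial lists (1 of 23, 10, 0.0419). By limma 26 genes changed, 25 up and 1 down, and 20 lists shifted (17 upward, 3 downward). The count was 5 without PTC C4d replicate 3, 62 without PTC C4d replicate 1, 94 with arrays weighted, 101 with the podocyte list mean as a covariate, 11 without the 10 arrays of lowest spread and 5 without the 6 biopsies of another visit tag.

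Against glomerular C4d biopsies without disease more genes passed the test. CXCL11 rose by 2.39 ± 0.46, SH2D1B by 1.51 ± 0.188 (adjusted p = 6.92e-08, 12 of 13), KLRD1, a receptor chain of NK cells, by 1.15 ± 0.231, and ITGAX, the integrin CD11c of dendritic cells and macrophages, by 1.24 ± 0.252. The endothelial genes SELE, an adhesion molecule of activated endothelium, VWF and CAV1, the coat protein of caveolae, rose by 1.06, 1.04 and 0.92. Among the falls were GABRB2, a receptor subunit for the transmitter GABA, CYP2J2, an epoxygenase of arachidonic acid, and F8, clotting factor VIII, by 0.75, 0.66 and 0.64. The rejection-associated (17 of 24 rose, 24 over the list alone, adjusted p = 1.74e-04), cytotoxic (16 of 23, 23, 0.0163), endothelial (13 of 23, 18, 0.0169) and interferon-gamma-inducible lists (18 of 22, 20, 0.0272) held with an estimated correlation. By limma 473 genes changed, 410 up and 63 down (1494 and 1986 with arrays weighted, 636 and 546 without the 10 arrays of lowest spread), and 16 lists shifted (14 upward, 2 downward). Glomerular C4d replicate 5 of the group without disease was the highest of its group in the interferon-gamma-inducible list, and without it the count was 762; without replicate 14 it was 981, and without PTC C4d replicate 2 it was 301.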

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

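The tests of array spread, of medulla, of collection order and of oxygen shortage were chosen only after the results they concern were seen; those of T cell content and of fewer glomeruli were set before.

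Among the genes that rose in PTC C4d biopsies over reference biopsies, array spread is argued against, since 81 of 81 stayed past the threshold with the spread as a covariate. A higher share of T cells in the core, with the rest unchanged, was tested with the T cell list mean as a covariate. With it 49 stayed, which met the rule set before for arguing against T cell content alone. The list mean measures T cell content with error and may adjust too little, and a call can stay while its change shrinks. The calls that stayed therefore do not exclude T cell content as the whole cause. The calls of the other 32 ended. Their median change went from 0.59 (SE 0.144) to 0.47 (SE 0.122), so they ended by a smaller change and not by a larger error. The median change of all 81 went from 0.69 to 0.53, so the shrinkage was not particular to these 32. Part of the rise of the 81 genes as a set may go with T cells. The genes of the T cell list with the highest intensities, which do not rank abundance between genes, were CD4 and CD3E. CD4 stood at 8.56 ± 0.529 against 8.09 ± 0.794 and CD3E at 8.53 ± 0.633 against 7.96 ± 1.13, neither past the test. None of the 20 genes of the T cell list stands on another list. The biological difference the design names, C4d along peritubular capillaries, stays open beside other cell types and treatment. Other immune cells and treatment were not tested. Of the 86 changed genes 36 kept their call with the collecting duct list mean as a covariate, and 65 with the podocyte list mean. The makeup of the core therefore stays open too.

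The podocyte list mean was lower in glomerular C4d biopsies with disease than in reference biopsies, by a difference of -0.44 (95% margin 0.192). Array spread is argued against: it went with the podocyte mean within groups (slope 0.74, margin 0.603) but differed by -0.00682 (margin 0.0667), and the podocyte difference with it as a covariate was -0.43 (margin 0.186). More medulla and less cortex in the core is argued against as the whole cause only as far as the proximal tubule mean follows cortex. The podocyte mean went with the proximal tubule mean within groups (slope 0.146, margin 0.0595). With that mean as a covariate the difference was -0.34 (margin 0.175), or -0.36 (margin 0.181) without the 2 biopsies with low proximal tubule genes. Without these 2 biopsies the proximal tubule means of the groups differed by -0.028. A covariate that measures cortex with error removes too little, so a part in the difference stays open. A collecting duct covariate, tried first, left -0.44 and decided nothing, since no slope on it could be shown (slope 0.00937, margin 0.129). Fewer glomeruli in the core cannot be told apart from a change within glomeruli: the mean of 6 other glomerular markers differed by -0.18 (margin 0.233), which leaves room for no difference and for one close to the podocyte list's, with CRHBP at -0.51, EHD3 at -0.36, ITGA8 at -0.18, HECW2 at -0.15, PLAT at 0.044 and TBX3 at 0.084, none past the test. Loss of podocytes or of their transcripts with disease may be a cause as well and was not tested apart.

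The immediate-early list mean was lower in reference than in native biopsies, by a difference of -0.61, with 16 genes fallen. Array spread is argued against, since 16 of the 16 stayed past the threshold with it as a covariate. With the running number as a covariate 14 stayed. That would argue against collection order as the whole cause only if the number marks this order, which is not stated, so collection order stays open. The calls of IER2 (-0.31 ± 0.103 to -0.27 ± 0.108) and CCN2 (-0.36 ± 0.129 to -0.33 ± 0.136) ended with a slightly smaller change and a slightly larger error. Oxygen shortage before implantation would leave hypoxia-responsive genes lower in reference biopsies, and their list mean differed by 0.082 (95% margin 0.158). Procurement and handling of the donor kidney go with the native group in every biopsy, so they cannot be told apart from transplantation itself.

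Among 204 tests of list means, genes and array spread in the groups of 4 and 10 biopsies, 16 had a biopsy whose gap to the nearest other was large for the group's range, and chance marks about 1 in 20. Of the native biopsies replicate 8 was the highest in 7 of them; its array had the lowest spread of the group, 1.80, and is 1 of the 10 arrays of low spread, and whether that raises these values was not tested. Its B cell and plasma cell list mean was 7.03 against 6.00 to 6.50 in the other 9, MS4A1, a B cell surface antigen, 7.25 against 4.48 to 5.86, SERPINA3 9.28 against 5.17 to 6.80, IDO1 6.37 against 4.46 to 5.29, UBD 8.81 against 6.42 to 7.46, PRF1 7.30 against 5.85 to 6.53 and LCN2 9.38 against 5.90 to 7.32. Native replicate 4 was the highest in SELE, 8.95 against 5.31 to 6.30.

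Of the minimal PTC C4d biopsies replicate 1 had the lowest proximal tubule list mean, 9.15 against 11.23 to 11.54, the lowest collecting duct list mean, 7.90 against 8.40 to 8.45, and the highest LYZ, 12.42 against 11.30 to 11.41. Replicate 4 was lowest in CXCL9, 9.16 against 10.69 to 10.85, and GBP5, 6.38 against 8.34 to 8.59. Replicate 3 was lowest in the podocyte genes PTPRO, 6.16 against 7.79 to 8.11, CLIC5, 6.87 against 8.41 to 8.44, and PODXL, 10.07 against 10.93 to 11.07.

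Transcript clusters outside the comparisons also differed between PTC C4d and reference biopsies: 11 of 1754 clusters with several symbols passed the threshold, all higher, and 10 of 7882 without a symbol, 8 higher and 2 lower. In proportion to the 86 genes changed, 7.75 and 34.8 would be expected, so clusters without a symbol passed less often. In PTC C4d over glomerular C4d without disease, 64 with several symbols (60 higher) and 47 without a symbol (35 higher) passed. Over glomerular C4d with disease 3 and 0 passed, and no cluster did in the remaining comparisons between transplant groups. Counts over native biopsies, where clusters without a symbol mostly fell, stand with those comparisons.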

How the results depend on the processing

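The settings with array spread, without arrays of low spread, without 2 biopsies with low proximal tubule genes, and with single biopsies left out of comparisons other than those of the minimal group were chosen after seeing the data; the others were set before. Averaging all clusters of a gene and eBayes with trend and robust options kept every count of genes within 1.5 times of its value. Single genes were followed where a named gene passed the threshold. The 11 preset genes in PTC C4d over reference and NPHS1 in glomerular C4d with disease over reference were followed as well. None of these turned its direction in the settings run for single genes, which leave out single biopsies of the minimal group alone. Of their values 5928 kept their side of the threshold, 462 lost it and 3 gained it. Other named values short of the threshold were not followed. The cause was not tested except where the setting itself tests fewer genes or biopsies.

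Counts of genes that moved by more than 1.5 times were as follows, against those in the report. Leaving out dim genes gave 0 in glomerular C4d without disease over reference biopsies, since PFKFB1 was among the genes left out. Array weights, which count arrays of noisier fit less, gave, over native biopsies, 8098 in reference, 8432 in PTC C4d, 6613 in minimal PTC C4d, 8295 in glomerular C4d with disease, 9077 in glomerular C4d without disease and 7309 in C4d-negative with disease. Its counts over reference biopsies were 1221 in PTC C4d, 27 in glomerular C4d with disease, 1042 in glomerular C4d without disease and 101 in C4d-negative with disease. In other comparisons it gave 710 for glomerular C4d with over without disease, 94 for PTC C4d over glomerular C4d with disease, 3480 for PTC C4d over glomerular C4d without disease and 5 for the interaction. The spread of the compared groups alone gave 2432 in minimal PTC C4d over native biopsies, and 43 in PTC C4d, 0 in glomerular C4d with disease and 0 in glomerular C4d without disease over reference biopsies. It also gave 12 for PTC C4d over glomerular C4d with disease. Quantile normalisation again gave 0 in glomerular C4d with disease and 0 in glomerular C4d without disease over reference biopsies. The running number as a covariate gave, over native biopsies, 5540 in reference, 3811 in minimal PTC C4d, 4908 in glomerular C4d with disease and 5061 in glomerular C4d without disease. Its counts over reference biopsies were 0 in glomerular C4d with disease. Between transplant groups it gave 2 for glomerular C4d with over without disease. Leaving out the 6 biopsies of another visit tag gave 10 in PTC C4d and 0 in glomerular C4d with disease over reference biopsies. Elsewhere it gave 2 for glomerular C4d with over without disease and 5 for PTC C4d over glomerular C4d with disease.

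The collecting duct covariate gave 3046 in minimal PTC C4d over native biopsies, and 45 in PTC C4d over reference biopsies. In other comparisons it gave 211 for PTC C4d over glomerular C4d without disease. The podocyte covariate gave 4142 in glomerular C4d without disease over native biopsies, and 0 in glomerular C4d with disease over reference biopsies. It also gave 101 for PTC C4d over glomerular C4d with disease and 756 for PTC C4d over glomerular C4d without disease. Requiring a change of at least 1.5 times gave, over native biopsies, 805 in reference, 1115 in PTC C4d, 905 in glomerular C4d with disease, 593 in glomerular C4d without disease and 691 in C4d-negative with disease. Its counts over reference biopsies were 50 in PTC C4d. Between transplant groups it gave 17 for PTC C4d over glomerular C4d with disease and 218 for PTC C4d over glomerular C4d without disease. The array spread covariate gave 1856 in reference, 735 in minimal PTC C4d and 852 in glomerular C4d without disease over native biopsies, and 206 in PTC C4d over reference biopsies. Elsewhere it gave 43 for PTC C4d over glomerular C4d with disease and 799 for PTC C4d over glomerular C4d without disease. Leaving out the 10 arrays of low spread gave, over native biopsies, 6443 in reference, 6304 in PTC C4d, 4234 in minimal PTC C4d, 7614 in glomerular C4d with disease, 6284 in glomerular C4d without disease and 6112 in C4d-negative with disease. Its counts over reference biopsies were 324 in PTC C4d and 0 in glomerular C4d with disease. In other comparisons it gave 1 for glomerular C4d with over without disease, 11 for PTC C4d over glomerular C4d with disease and 1182 for PTC C4d over glomerular C4d without disease. Leaving out the 2 biopsies with low proximal tubule genes gave 1701 in glomerular C4d with disease over native biopsies, and 0 in glomerular C4d with disease over reference biopsies. Of the 86 genes of PTC C4d over reference, all 86 also passed with array weights and with the spread covariate, 85 without arrays of low spread, 79 after quantile normalisation, 58 with the running number, 36 with the collecting duct covariate and 10 without the biopsies of another visit tag.

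Counts of lists moved as follows. An estimated correlation gave, over native biopsies, 1 in reference, 3 in PTC C4d, 0 in minimal PTC C4d, 1 in glomerular C4d with disease, 1 in glomerular C4d without disease and 1 in C4d-negative with disease. Its counts over reference biopsies were 6 in PTC C4d, 1 in minimal PTC C4d, 1 in glomerular C4d with disease, 0 in glomerular C4d without disease and 1 in C4d-negative with disease. It also gave 1 for glomerular C4d with disease over C4d-negative with disease, 0 for glomerular C4d with over without disease, 6 for PTC C4d over glomerular C4d with disease and 4 for PTC C4d over glomerular C4d without disease. Fry gave, over native biopsies, 8 in glomerular C4d without disease. Its counts over reference biopsies were 9 in PTC C4d, 1 in minimal PTC C4d, 1 in glomerular C4d with disease, 0 in glomerular C4d without disease and 1 in C4d-negative with disease. Between transplant groups it gave 1 for glomerular C4d with disease over C4d-negative with disease, 0 for glomerular C4d with over without disease, 9 for PTC C4d over glomerular C4d with disease and 10 for PTC C4d over glomerular C4d without disease. The podocyte covariate gave 11 for glomerular C4d with disease over native and 6 for glomerular C4d with over without disease lists, the spread covariate 24 for minimal PTC C4d over native, and leaving out the 2 biopsies with low proximal tubule genes 14 for glomerular C4d with disease over reference.

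With 1 biopsy left out at a time, genes changed ran as follows, and each replicate whose absence moved a count by more than 1.5 times is named with the count without it in brackets. Reference over native ran from 2229 to 5314, with native 5 (2229). PTC C4d over reference ran from 20 to 171, with PTC C4d 2 (22), 3 (20), 5 (41), 9 (49), and reference 5, 13 and 22 (57), 6 (54), 8 (157), 11 and 17 (55), 16 (138), 18 (56), 21 (171), 23 (168). Glomerular C4d with disease over reference ran from 0 to 7, with glomerular C4d with disease 2, 3, 4, 5, 8, 9, 11 and 12 (0), 10 (7), and reference 1, 2, 3, 4, 5, 6, 8, 9, 11, 13, 14, 18, 19, 20, 23, 24 and 25 (0), 7 and 17 (1). Glomerular C4d without disease over reference ran from 0 to 1, with glomerular C4d without disease 13 (0). Glomerular C4d with over without disease ran from 0 to 3, with glomerular C4d with disease 7 (2), 8 (1), 10 and 12 (3), and glomerular C4d without disease 1, 2 and 14 (1), 5 and 7 (2). PTC C4d over glomerular C4d with disease ran from 5 to 62, with PTC C4d 1 (62), 2 (7), 3 (5), 4 (15), 5 (17), and glomerular C4d with disease 5 and 7 (10), 8 (8), 9 (48), 12 (6), and over glomerular C4d without disease from 301 to 981, with PTC C4d 2 (301), and glomerular C4d without disease 5 (762), 14 (981). Minimal PTC C4d over native ran from 142 to 1510, with minimal PTC C4d 1 (142), 2 (433), 3 (407). C4d-negative with disease over reference and glomerular C4d with disease over C4d-negative with disease stayed at 0 in each fit, and minimal PTC C4d over reference did with each of its own 4 biopsies left out. The other comparisons with native biopsies were not refitted in this way, and for the minimal group no native or reference biopsy was left out. No paired analysis was possible because only 1 running number is shared, by a native and a reference biopsy, and the labels do not say what it marks.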

Other observations

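The genes and biopsies in the next 3 paragraphs and the relation with array spread were chosen after their values were seen, and the tests by random splits were set before.

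A haemoglobin gene and a mast cell gene rose in every transplant group over native biopsies, while no other measured member of their lists did. HBB, the beta chain of haemoglobin, rose by 1.95, 2.65, 2.84, 2.20, 2.46 and 2.45 in reference, PTC C4d, minimal PTC C4d, glomerular C4d with disease, glomerular C4d without disease and C4d-negative biopsies with disease. CPA3, a carboxypeptidase of mast cell granules, rose in the same order by 1.08, 1.21, 2.02, 1.51, 1.17 and 1.62. Each was the 1 gene to rise of 7 in the erythroid and 4 in the mast cell list (1 adjusted over the list alone as well), and neither list shifted in any group (adjusted p = 0.178 to 0.813 and 0.114 to 0.838). COX5B, a subunit of the last complex of the respiratory chain, changed by -0.87, -0.95, -0.95, -0.85, -0.61 and -0.89, past the test in each.

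Single biopsies stood apart from their group in immune genes. In the interferon-gamma-inducible list replicate 5 of the glomerular C4d biopsies without disease had a mean of 9.82, and the next highest of its group 8.13. Its means in the cytotoxic and NK cell, macrophage and monocyte and antibody-mediated rejection-associated lists were 7.45, 9.58 and 7.81, the highest of its group in each. Among PTC C4d biopsies replicate 1 had the lowest means of the interferon-gamma-inducible and cytotoxic and NK cell lists, 7.93 and 5.96, and replicate 12 those of the endothelial and antibody-mediated rejection-associated lists, 7.67 and 7.15; that array's spread was 1.75, the lowest of the group.

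The first principal component of all arrays held 36.2 percent of their variance and the second 14.8 percent. The first went with the spread of the 92 arrays, with Pearson's r of 0.983 and Spearman's rho of 0.882 (permutation p = 1e-04 each, the smallest that the permutations can give; 1 relation was tested). Without the 2 arrays farthest from the median spread r was 0.979, and over the 82 arrays without those of low spread 0.923, so the largest axis of variation goes with an array measure. Of the 10 arrays with a spread under 1.93, 2 were native, 1 PTC C4d, 2 glomerular C4d with disease, 1 glomerular C4d without disease, 2 C4d-negative with disease and 2 reference biopsies.

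Each comparison was repeated with 100 splits of its biopsies into groups of the same sizes, the real split among them, and the genes changed were counted in each. The rule set before took under 5 of 100 splits reaching the real count as arguing against chance. With 100 splits in each of 16 comparisons and no correction for their number, it cannot exclude chance. Over native biopsies only 1 split, the real one, reached the real count for reference (3625, highest other 1981), PTC C4d (3050, 1660), minimal PTC C4d (1232, 704) and glomerular C4d with disease (3216, 2090), which meets the rule. Glomerular C4d without disease (2745, 5490) and C4d-negative with disease (1998, 4266) met it with 2 splits each, although the other one called more genes than the real. Over reference biopsies PTC C4d met it (86, 50, 1 split). For glomerular C4d with disease 2 splits reached the 3 genes, the real one among them, which meets it. The other split gave 228, and the count was 0 in 25 of 38 fits that left out 1 biopsy. Glomerular C4d without disease did not meet it (1, 9, 6 splits). PTC C4d over glomerular C4d with disease (26, 54, 3 splits) and without disease (473, 1384, 2 splits) met it, though in each another split called more genes. In 5 comparisons limma called 0 genes, which each of the 100 splits reaches whatever the groups, so the splits say nothing about chance there: minimal PTC C4d over reference (highest other 66, 276 genes at an unadjusted p under 0.05), C4d-negative with disease over reference (494, 775), glomerular C4d with over without disease (450, 947), glomerular C4d with disease over C4d-negative with disease (0, 251) and the interaction (0, 346). Splits that call several times the real count, 228 against 3, 9 against 1 and 1384 against 473, point to a structure of the samples beside the groups. So do 5490 against 2745, 4266 against 1998 and 54 against 26, about 2 times the real count, and the 494, 450 and 66 genes in comparisons where the real split called none. Array spread is a candidate for it, and whether those splits follow it was not tested.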
